A study of Homo sapiens and Mus musculus with 9 samples.

How the data were processed

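The series holds 9 samples: 6 bulk RNA-seq libraries of human NK cells and 3 droplet single-cell RNA-seq libraries of mouse lung cells sorted as NK cells. For the bulk samples, the authors deposited a table of whole-number read counts per gene symbol. Per the labels, reads were aligned with STAR 2.5, and DESeq2 is listed with the version written as 3.5. The labels give mm9 as the genome build of these samples, but the table carries human gene symbols, so the build behind it is not given in the sources used here and no coordinates are printed. The annotation and the program that counted the reads are not given either. For each mouse sample, the authors deposited a matrix of UMI counts per gene and cell barcode made with Cell Ranger and build mm10, per the labels; the Cell Ranger version is not stated. Only called barcodes are present, so the RNA in empty droplets could not be measured.

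The bulk table has 25435 gene symbols. XIST, its neighbourhood and the Y-linked genes (108 symbols) were withheld for the human samples. A further 28 names had been turned into dates by a spreadsheet and were kept as they stand, and the table lists 0 mitochondrially encoded genes. Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr on the groups (13299 genes tested) and the robust quasi-likelihood test of 7C6 against isotype, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held the group alone. The labels name 1 volunteer as the source of the NK cells and no separate cultures for the replicates, so the p-values measure the spread between these samples, which may be technical, and say nothing about other donors. A simulation drew counts from the gene means, library sizes and dispersion trend of these data, with known changes added. It recovered 78% of genes changed 1.5-fold and 99% of genes changed 2-fold, with 8 false calls among 185. The simulated counts lacked the spread particular to single genes or libraries, so recovery in the real libraries may be lower. Values per gene are given as CPM (counts scaled by the library total), mean ± SD over 3 libraries, with the log2 fold change and its standard error (SE).

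Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 21 human lists that could be tested. The rotation test fry of the same package, directional and mixed, was an alternative. The 23 human lists cover effector cytokines and chemokines, cytotoxic granule and death ligand genes, activating receptors, inhibitory receptors, activation markers, immediate early genes, NF-kB targets, type I interferon and interferon gamma response, IL-2 and STAT5 targets, proliferation, glycolysis, ribosome biogenesis, sterol synthesis, the unfolded protein response, heat shock, NKG2D ligands, melanoma cell markers, markers of T, B and myeloid cells, platelet and erythroid markers, and mitochondrially encoded genes. For each list the text gives the number of members past the threshold over all genes tested and the number adjusted over the list alone.

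Mouse cells were kept with at least 200 detected genes and at most 10% of UMIs from mitochondrially encoded genes, and doublets were called per library by Scrublet in scanpy 1.11.5. Scrublet marked 2, 5 and 0 cells in the 7C6, isotype and naive libraries, too few for the calls to have worked, so the lists were also computed without cells above 3 times the median UMI of their library. The 3 libraries were clustered together on log-normalised values (Leiden resolution 0.5, 30 neighbours, 30 principal components, 2000 variable genes), and a cluster took the name of a class other than NK when at least 3 markers of that class stood among its top 25 genes and no other class had more among its top 10. A cluster with fewer such markers was named NK-like when at least 3 NK markers reached 50 CPM in its sum, a mark that every cluster met, so that NK-like means that no other class was found. Clusters named T-like, B-like, epithelial-like or macrophage-like were set aside. The remaining NK-like, ILC1-like and proliferating-like cells are called the compared cells: 3314 in the 7C6 library, 2420 in the isotype library and 2674 in the naive library. Keeping the ILC1-like and proliferating-like cells and asking for 3 markers were decided after the data were seen. The fold measure used to rank a cluster's genes was also changed after its result was seen: a fold of pooled sums had named cluster 1 neutrophil-like because 11 naive cells carried its S100a8 UMIs, and a mean over cells on the log scale replaced it; the values with cluster 1 also set aside are given under the alternatives.

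UMIs of the compared cells were summed per library and scaled to CPM over the 27998 genes of the matrix. For 56 symbols found on more than 1 matrix line, the line with more UMIs was used. With 1 library per group no test was possible. Genes are given as CPM with exact Poisson intervals (95%), and shares of cells with exact Clopper-Pearson intervals (95%), which cover counting error only and not the difference between animals or libraries. Each of 31 mouse lists is given as the median over its members with at least 10 CPM in any library of the log2 ratio of (CPM + 1), with its percentile among 10000 random lists of the same size matched on expression in 20 bins; lists with fewer than 3 such members have no median. Simulated shifts of 0.5 and 1 on the log2 scale in a list of 15 genes were both placed at percentile 100, and no shift at 5.91. Shares of cells with a UMI are given before and after each cell was thinned to 1000 UMIs; the 54 cells of the 7C6 library and 63 of the isotype library with fewer UMIs were left out of the thinned shares. The share in B-, epithelial- and macrophage-like cells serves as background.

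The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. In the bulk data the rule took the 12 largest rises and the 12 largest falls among genes past the threshold with at least 1 log2 CPM, up to 4 members per list with the smallest p past the threshold (or the 2 with the smallest p, as values), and KLRK1. In the mouse data it took, for 7C6 versus isotype and isotype versus naive, the 10 largest and 10 smallest log2 ratios among genes with at least 50 CPM in either library, up to 4 members per list, and Klrk1. Some genes that this rule names are not reported here. The alternatives fixed at that time were DESeq2 1.42.0, other normalisations, other low-count filters, limma voom, the replicate number as a block, each library left out in turn, stricter thresholds, and other settings of the set tests; for the mouse lists, other cell filters, thinning, TMM factors, other totals, weighting each cell alike, pseudocounts of 0.1 and 5 CPM, and minimums of 1 and 50 CPM; and for shares, Leiden resolutions of 0.3 and 1. Alternatives added later were a loess correction of each bulk library for GC content and transcript length (reference annotation matched by symbol), library quality weights, the limit on UMIs per cell and the set-aside of cluster 1. The reads themselves were not used here.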

Results

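NKG2D, encoded by KLRK1, is an activating receptor of NK cells whose human ligands MICA and MICB are shed from the surface of tumour cells. The antibody 7C6 binds MICA/B and, per the title of the series, inhibits that shedding. It was used as 7C6-hIgG1 in culture and as 7C6-mIgG2a in mice. Gene expression was measured in NK cells that met tumour cells carrying this antibody or an isotype control, once in culture and once in mice. In culture, human NK cells activated with IL-2 were mixed with A375 cells, a human melanoma line, for 6 hours at 5 NK cells per tumour cell, after the A375 cells had been kept for 48 hours with 10 ug/ml of 7C6 or isotype antibody. The NK cells were then sorted again, and 3 bulk RNA-seq libraries were made per group. The isotype libraries held 24528563, 27587281 and 24488279 counts and the 7C6 libraries 21667478, 17178379 and 21516312. In mice, lung cells with the surface phenotype of NK cells (NK1.1 and NKp46 positive, CD3e and TCRb negative) came from animals given B16 melanoma cells that carry MICA and treated with 7C6 on days 1 and 2, from such animals treated with isotype antibody, and from naive animals. There was 1 droplet library per group, with 3403 cells in the 7C6 library, 2685 in the isotype library and 3820 in the naive library, and with 9214348, 7348151 and 11672632 UMIs.

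The bulk comparison asked what changes in human NK cells when the tumour cells they meet have been kept with 7C6 in place of the isotype antibody. Several genes of NK cell stimulation rose. Transcripts of the cytokine interferon gamma (IFNG) went from 16.3 ± 1.24 to 39.9 ± 0.493 CPM (counts scaled by library total; mean ± SD, n = 3), those of the costimulatory receptor CD137 (TNFRSF9) from 82.1 ± 11.9 to 371 ± 42.8 CPM, and those of CRTAM, an adhesion receptor of activated cytotoxic lymphocytes, from 71.0 ± 8.14 to 297 ± 15.6 CPM. Melanoma cell markers fell, among them FN1 (fibronectin), from 7.68 ± 2.28 to 1.73 ± 0.741 CPM, and SPARC, a matrix protein, from 26.3 ± 1.31 to 10.3 ± 2.59 CPM. Of 13299 genes tested, 600 passed the threshold, 316 higher and 284 lower with 7C6. This count was 116 without isotype replicate 1, 175 without isotype replicate 2, 208 without isotype replicate 3 and 201 without 7C6 replicate 1, and it was 1994 without 7C6 replicate 2, the library with the fewest counts.

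Among the largest rises were FNDC5, the precursor of irisin (log2 fold change 3.29 ± 0.24 SE, adjusted p = 0.00059), MFSD2A, a lysophospholipid transporter (2.60 ± 0.19, adjusted p = 0.00059), RGS16, a regulator of G protein signalling (2.37 ± 0.17, adjusted p = 0.00059), and MIR155HG, the host transcript of a microRNA of lymphocyte activation (2.26 ± 0.16, adjusted p = 0.00059). TNFRSF9 rose by 2.18 ± 0.13 and CRTAM by 2.06 ± 0.10, with adjusted p of 0.00031 and 0.00014. RRAD, a small GTPase, rose by 1.88, the lysosomal membrane gene LAMP3 by 1.80 and TRAF1, an adaptor of TNF receptor signalling, by 1.79. TMEM88 rose by 2.08 (adjusted p = 0.017), a call that ended without any 1 of the isotype libraries or 7C6 replicate 1 (adjusted p up to 0.089). Several of these genes stood at low levels. Mean CPM went from 0.404 to 4.03 for FNDC5, from 1.70 to 10.4 for MFSD2A, from 1.39 to 5.18 for RRAD, from 1.27 to 4.41 for LAMP3 and from 1.00 to 4.30 for TMEM88. All 58 named genes past the threshold had no overlap between the 3 libraries of 1 group and the 3 of the other, which chance gives for 10% of genes not chosen by a test; these were chosen by the test, so this adds no evidence. Of these 58, 33 passed the threshold in each of the 6 fits with 1 library left out.

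Many cytokine and activation genes rose. Of 18 effector cytokine and chemokine genes tested, 12 rose and 0 fell (14 and 1 adjusted over the list alone), including the granulocyte-macrophage growth factor CSF2 (1.40 ± 0.16, adjusted p = 0.0044) and the chemokines CCL3 (0.81 ± 0.08, adjusted p = 0.0029) and CCL4 (0.55 ± 0.06, adjusted p = 0.0044). The list ranked high against other genes (camera, adjusted p = 2.3e-10), with adjusted p = 0.20 with an estimated correlation. Of 14 activation markers and costimulatory receptors, 9 rose and 0 fell (9 and 1 adjusted over the list alone), with CD83 at 1.58 ± 0.09 (adjusted p = 0.00028) and the IL-2 receptor chain IL2RA at 1.42 ± 0.09 (adjusted p = 0.00036). The adjusted p of this list was 6.6e-08, and adjusted p = 0.20 with an estimated correlation. Among 21 NF-kB targets 15 rose and 0 fell (15 and 0 adjusted over the list alone), such as the adhesion molecule ICAM1 (1.24 ± 0.09) and NFKB2 (1.12 ± 0.09), with a list adjusted p of 2.2e-13, and adjusted p = 0.20 with an estimated correlation. Of 27 immediate early genes 11 rose and 0 fell (16 and 2 adjusted over the list alone), among them the transcription factor EGR2 (1.25 ± 0.09), the phosphatase DUSP5 (1.24 ± 0.12), IER3 (1.06 ± 0.12) and IER5 (0.94 ± 0.07). The list adjusted p was 3.9e-07, and adjusted p = 0.20 with an estimated correlation.

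Of 17 IL-2 and STAT5 targets, 6 rose and 0 fell (8 and 1 adjusted over the list alone), including the survival gene BCL2L1 (1.11 ± 0.10, adjusted p = 0.0013), the kinase PIM2 (0.85 ± 0.08, adjusted p = 0.0021) and the cytokine LTA (1.32 ± 0.18, adjusted p = 0.0081, and 0.058 without isotype replicate 1). The list gave adjusted p = 0.0018, and adjusted p = 0.26 with an estimated correlation. Of 20 interferon gamma response genes 2 rose and 0 fell (4 and 0 adjusted over the list alone): ICAM1, which is also an NF-kB target, and WARS, a tRNA synthetase induced by interferon (0.56 ± 0.09, adjusted p = 0.012, and up to 0.093 without any 1 of the isotype libraries). The list gave adjusted p = 0.0026, and adjusted p = 0.26 with an estimated correlation. Of 28 type I interferon response genes only OAS3, an antiviral enzyme, rose (0.75 ± 0.08, adjusted p = 0.0040; 1 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.98). Of 20 ribosome biogenesis genes RRS1 rose (0.45 ± 0.09, adjusted p = 0.034; 8 and 0 adjusted over the list alone). That list gave adjusted p = 4.0e-05, and adjusted p = 0.26 with an estimated correlation.

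The genes of killing and of NK receptors moved little. Of 19 cytotoxic granule and death ligand genes, STX11, a syntaxin of granule release, rose (0.62 ± 0.10, adjusted p = 0.012; 1 and 0 adjusted over the list alone) and 18 did not pass. The list gave adjusted p = 0.039, and adjusted p = 0.39 with an estimated correlation. It did not pass in the directional rotation test fry (0.061), or without 7C6 replicate 2 (0.056), 7C6 replicate 3 (0.050), isotype replicate 1 (0.10) or isotype replicate 2 (0.077). Of 22 activating receptors and adaptors, SLAMF7 (0.40 ± 0.06, adjusted p = 0.012) and CD160 (0.58 ± 0.09, adjusted p = 0.014) rose (3 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.19). KLRK1 itself stood at 3.25 ± 0.331 and 3.19 ± 1.47 CPM (log2 fold change -0.01 ± 0.30, adjusted p = 0.99); reads of this gene may be shared with a read-through transcript of the same locus. Of 16 inhibitory receptors the checkpoint receptor HAVCR2 (TIM-3) rose (0.49 ± 0.07, adjusted p = 0.0084; 2 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.72). The calls of STX11 and SLAMF7 ended without any 1 of the isotype libraries or 7C6 replicate 1, that of CD160 without any 1 of the isotype libraries, and that of HAVCR2 without isotype replicate 1, isotype replicate 3 or 7C6 replicate 1, with adjusted p up to 0.090, 0.093, 0.095 and 0.071.

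Metabolic and stress lists held few calls. Of 18 glycolysis genes the pyruvate kinase PKM (1.07 ± 0.10, adjusted p = 0.0021) and the lactate exporter SLC16A3 (0.66 ± 0.09, adjusted p = 0.0087) rose (2 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.20). Of 17 sterol synthesis genes INSIG1, a regulator of sterol sensing, rose (0.38 ± 0.09, adjusted p = 0.048; 1 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.69). Of 14 genes of the unfolded protein and integrated stress response CHAC1, a glutathione-degrading enzyme, rose from a low level (0.324 ± 0.119 to 1.42 ± 0.211 CPM, adjusted p = 0.0087; 1 and 0 adjusted over the list alone). The list gave adjusted p = 0.019, adjusted p = 0.31 with an estimated correlation and 0.056 in fry. Of 11 heat shock genes 0 passed (1 and 0 adjusted over the list alone), and the smallest p belonged to DNAJA1 (0.31 ± 0.07, adjusted p = 0.056) and HSPH1 (0.21 ± 0.07, adjusted p = 0.13). That list gave adjusted p = 0.0084, with adjusted p = 0.39 with an estimated correlation, 0.081 in fry and 0.052 without 7C6 replicate 2. Leaving out isotype replicate 1 ended the calls of SLC16A3, INSIG1, CHAC1 and RRS1, a ribosome assembly factor, with adjusted p up to 0.067, 0.23, 0.059 and 0.19 over the left-out libraries. Isotype replicate 2 also ended those of SLC16A3, INSIG1 and RRS1, and isotype replicate 3, 7C6 replicate 1 and 7C6 replicate 3 those of INSIG1 and RRS1. INSIG1 also did not pass with RLE size factors (adjusted p = 0.056) or the stricter low-count filter (0.057).

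Melanoma markers were present in the sorted NK cell libraries and fell with 7C6. Of 22 melanoma cell markers tested 16 fell and 0 rose (0 rose and 22 fell adjusted over the list alone), among them SPARC (-1.36 ± 0.16, adjusted p = 0.0044), the cyclin CCND1 (-1.34 ± 0.18, adjusted p = 0.0078), TIMP3, an inhibitor of matrix proteases (-1.72 ± 0.23, adjusted p = 0.0078, and 0.054 without isotype replicate 1), and FN1 (-2.18 ± 0.31, adjusted p = 0.0087, and 0.051 without 7C6 replicate 1). The list gave adjusted p = 8.0e-17, and adjusted p = 0.20 with an estimated correlation. The mean log2 CPM of these markers was 3.02, 2.67 and 2.67 in the isotype libraries and 1.22, 1.82 and 1.38 in the 7C6 libraries. Among genes past the threshold with at least 1 log2 CPM, the 12 largest falls began with the receptor kinase EPHA2 (-2.23 ± 0.29, adjusted p = 0.0067), FN1, the cadherin FAT1 (-2.02 ± 0.24, adjusted p = 0.0047) and the adhesion molecule KIRREL (-2.01). They were followed by the transcription factor TEAD1 (-1.90), GPRC5A (-1.84), SYTL5 (-1.84), the caveolin CAV1 (-1.83), the receptor kinase AXL (-1.79), CAMSAP2 (-1.78), HR (-1.77) and the scaffold protein AKAP12 (-1.76). Leaving out isotype replicate 1 ended the calls of KIRREL, TEAD1, GPRC5A, CAV1, AXL, HR and AKAP12, with adjusted p up to 0.051, 0.054, 0.12, 0.054, 0.060, 0.16 and 0.058 over the left-out libraries. Leaving out 7C6 replicate 1 also ended those of TEAD1, GPRC5A, AXL, HR and AKAP12, and isotype replicate 2, isotype replicate 3 and 7C6 replicate 3 those of GPRC5A and HR.

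Some proliferation genes fell alongside. Of 27 tested 4 fell and 0 rose (0 rose and 15 fell adjusted over the list alone): the topoisomerase TOP2A (-0.61 ± 0.09, adjusted p = 0.0082), the mitotic kinases BUB1B (-0.80 ± 0.11, adjusted p = 0.0084) and PLK1 (-1.01 ± 0.21, adjusted p = 0.037), and MKI67 (-0.72 ± 0.14, adjusted p = 0.026). The list gave adjusted p = 2.1e-07, and adjusted p = 0.26 with an estimated correlation. These genes are also active in dividing tumour cells. Within the groups, 22 of the 27 had a positive slope on the melanoma markers after correction for GC content and length (median 0.26). Of 11776 genes not past the threshold, 5764 had a positive slope (median -0.01, upper quartile 0.23). Proliferation genes move together and are not independent, so the slopes do not settle which cells the fall comes from. The calls of TOP2A and BUB1B ended without isotype replicate 1 or isotype replicate 2 (adjusted p up to 0.062 and 0.058). Those of MKI67 (up to 0.12) and PLK1 (up to 0.18) ended without either of these or without 7C6 replicate 1 or 7C6 replicate 3, and that of PLK1 also without isotype replicate 3.

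Markers of other blood cells mostly did not pass. Of 6 T cell markers 0 passed, with CD3G at -0.66 ± 0.21 (adjusted p = 0.12) and CD8B at -0.58 ± 0.24 (adjusted p = 0.20), and the list gave adjusted p = 0.18, and 0.021 without 7C6 replicate 2. B cell genes CD79B (-0.05 ± 0.14, adjusted p = 0.84) and CD79A (-0.05 ± 0.24, adjusted p = 0.91) did not pass, and 2 genes were too few for a list test. Of 3 myeloid markers 0 passed, with CST3 at -0.32 ± 0.15 (adjusted p = 0.25) and CD68 at 0.17 ± 0.12 (adjusted p = 0.42), and the list gave adjusted p = 0.53. Of 3 platelet and erythroid markers the alpha-globin genes HBA1 (2.65 ± 0.33, adjusted p = 0.0054) and HBA2 (1.96 ± 0.24, adjusted p = 0.0048) rose, with a list adjusted p of 0.0084, and adjusted p = 0.26 with an estimated correlation. Their means went from 1.07 to 6.78 and from 0.852 to 3.37 CPM. The genes are near-identical and may share reads, so they may not be separate signals. The counts adjusted over the list alone were 0 and 0 for T, B and myeloid cells and 2 and 0 for the globin list. Of 5 NKG2D ligand genes ULBP1 rose from 0.181 ± 0.0690 to 0.814 ± 0.0390 CPM (adjusted p = 0.012; 2 and 0 adjusted over the list alone), a call that ended without isotype replicate 1, isotype replicate 3 or 7C6 replicate 1 (adjusted p up to 0.071). The ligand list did not pass (adjusted p = 0.056), but passed without 7C6 replicate 1 (0.031), isotype replicate 1 (0.046) or isotype replicate 2 (0.021). No mitochondrially encoded gene was in the table.

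Gene length and base composition moved with the calls. The genes that rose had a median transcript length of 3162 bases and a GC content of 57.0%, those that fell 5509 bases and 46.3%, and all tested genes 3610 bases and 48.1%. In 7C6 replicate 2, the deviation from the mean of all other libraries correlated across genes with GC content (Spearman's rho 0.58) and with length (rho -0.48). That mean includes the isotype libraries, so the group difference is part of this deviation, and genes are not independent replicates. With each library corrected for both, an alternative added after the data were seen, 285 of 306 genes that rose and 218 of 276 that fell were still past the threshold in the same direction, and 1428 genes passed in all.

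**Figure D1:**
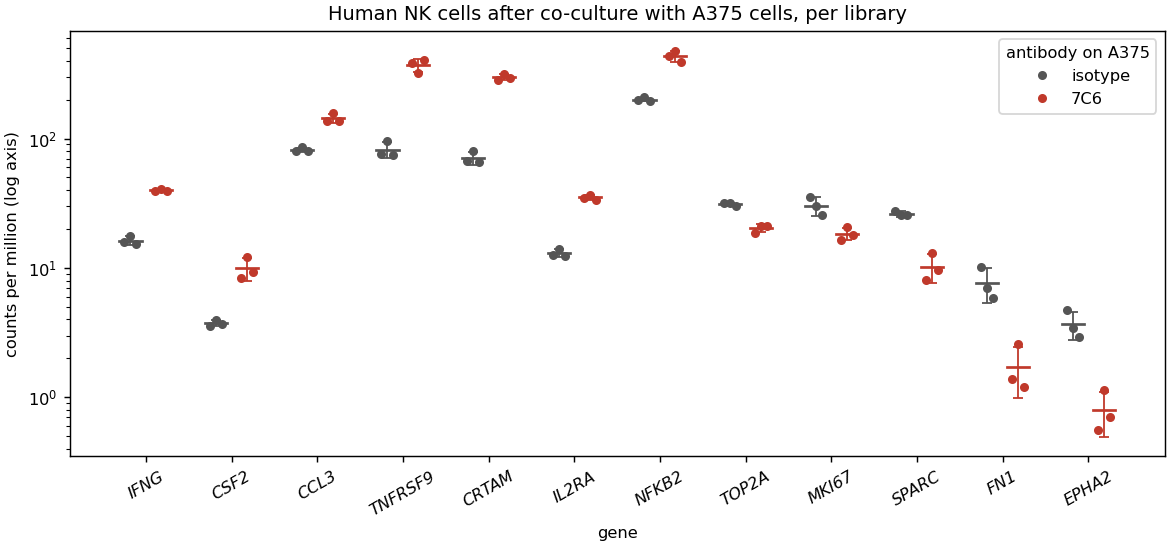
CPM (log axis) of 12 genes in each human NK cell library after co-culture with A375 cells kept with isotype antibody or 7C6; points are libraries (n = 3 per group), horizontal lines are means and bars are the SD. IFNG went from 16.3 to 39.9 CPM and TNFRSF9 from 82.1 to 371 CPM, while SPARC went from 26.3 to 10.3 CPM.

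In mice, the comparison of the 7C6 and isotype libraries asked how lung NK cells differ after treatment of tumour-bearing animals with the antibody. Genes of mature, cytotoxic NK cells were higher in the 7C6 library, and genes of immature NK cells and of tissue-resident group 1 innate lymphoid cells (ILC1) were lower. The granule protease granzyme A (Gzma) stood at 16663 CPM (95% interval 16578 to 16748) in the 7C6 library, 2351 (2314 to 2388) in the isotype library and 2587 (2552 to 2622) in the naive library. Granzyme B (Gzmb) stood at 1332 (1308 to 1356), 304 (291 to 318) and 209 (199 to 219) CPM, and Il7r, the IL-7 receptor of ILC and immature cells, at 27.2 (23.9 to 30.8), 273 (261 to 286) and 213 (203 to 223). These values mix cells of different clusters. Cluster 0, whose top genes include Gzma, Cma1 and Klrg1, held 69.9% of the compared 7C6 cells, 6.28% of the isotype cells and 5.68% of the naive cells, whereas the ILC1-like cluster 2 held 8.60%, 58.2% and 59.7%. Cluster 1, also NK-like, held 18.9%, 32.1% and 32.0%. The name of cluster 2 rests on top genes such as Tmem176b and Cxcr6, and Ltb and Xcl1 of the immature NK cell list also stand there. Before thinning, Cxcr6 was seen in 35.4% of isotype and 41.9% of naive compared cells, but Itga1 of the ILC1 list in 3.26% and 3.96%. Low detection can reflect depth, so whether the cells of cluster 2 are ILC1 was not settled. With 1 library per group, the difference between animals or libraries is not measured, and the intervals cover counting error only.

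Other genes with large ratios of 7C6 to isotype were the chemokine receptor Cx3cr1 (log2 ratio 3.77), the mast cell protease gene Cma1 (3.71), the inhibitory receptor and maturation marker Klrg1 (3.40), the egress receptor S1pr5 (3.25) and the transcription factor Zeb2 (2.56). Gpx8 (4.41), Rac3 (3.32), Borcs7 (2.48) and Serpinb9b (2.30) complete the 10 largest with Gzma (2.82). The 10 smallest were Il7r (-3.28), granzyme C (Gzmc, -2.96), the chemokine gene Ccl1 (-2.96), Serpina3f (-2.77), Inpp4b (-2.70), the oxysterol receptor Gpr183 (-2.58), Ckb (-2.55), the tetraspanin Cd81 (-2.52), Tmem176a (-2.50) and Tmem176b (-2.43). Of 15 mature NK cell genes 14 were higher in the 7C6 library, with a list median of 1.24 (percentile 100 among random lists). All 13 measured ILC1 genes were lower (median -2.43, percentile 0), and 14 of 15 immature NK cell genes were lower (median -1.27, percentile 0), among them the lymphotoxin gene Ltb (-2.32), the chemokine gene Xcl1 (-1.83) and Emb (-1.78). The median over all genes was -0.05.

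Of 18 cytotoxic granule and death ligand genes 13 were higher (median 0.49, percentile 100), with Gzma and Gzmb (2.13) high and Gzmc and the death ligand Tnfsf10 (-2.59) low. Of 22 genes listed as activating receptors and adaptors 16 were higher (median 0.63, percentile 100). The signalling chain Cd247 (1.53) was among them, while Cd226 was lower (-1.39). The Ly49 receptors Klra8 (1.36) and Klra9 (1.28) were also higher, but near-identical family members make their counts uncertain. Klra9 encodes an inhibitory receptor, so the list does not hold activating receptors alone. In clusters found without the listed genes and weighed alike in both libraries, a comparison added after the first result, the cytotoxic median was 0.15 (interval over members -0.06 to 0.50) and the activating receptor median 0.28 (-0.02 to 0.40). Klrk1 stood at 1425 (1400 to 1450), 1506 (1477 to 1536) and 1641 (1613 to 1669) CPM in the 7C6, isotype and naive libraries. The 15 inhibitory receptors were divided, with Klrg1 high and Lilrb4a (-2.32), Pdcd1 (-2.11) and Ctla4 (-2.06) low (median -0.22, percentile 5.66; the mean was 0.02, of the other sign).

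Pooled over clusters, most members of the cytokine, activation, immediate early, NF-kB and IL-2 lists were lower in the 7C6 library. Effector cytokines and chemokines had a median of -0.95 (percentile 0; 11 of 16 lower), with Cxcl10 (-3.15), Ccl1, Ltb and Areg (-2.28) lowest, while Ifng stood at 270 (260 to 282) and 280 (267 to 293) CPM. Of 10 activation markers 9 were lower (median -0.86, percentile 0), including Cd83 (-2.83), Il2ra (-2.28), Ly6a (-1.70) and Cd44 (-0.88). Of 21 immediate early genes 20 were lower (median -0.72, percentile 0), such as Fosb (-2.41), Fos (-1.74), Nr4a3 (-1.70) and Myc (-1.41). Of 21 NF-kB targets 17 were lower (median -0.88, percentile 0), such as Bcl2a1d (-2.24), Bcl2a1b (-1.51) and Tnfaip8 (-1.22). IL-2 and STAT5 targets had a median of -0.47 (percentile 0), with Socs2 (-2.40), Lta (-1.96) and Cish (-1.78) low. TGF-beta response genes had a median of -1.21 (percentile 0), with Pmepa1 (-2.12), Nt5e (-1.99) and the integrin Itga1 (-1.25) low. All 10 heat shock genes were lower (median -0.74, percentile 0.01), among them Hspb1 (-1.27), Hsph1 (-1.08), Dnaja1 (-1.01) and Dnajb1 (-0.86).

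Type I interferon response genes had a median of -0.46 (percentile 0.04), with Ifit1 (-1.82), Ifit3 (-1.45), Ifi27l2a (-1.14) and Rtp4 (-1.03) low; the median was 0.09 over members with at least 50 CPM. Ribosome biogenesis genes had a median of -0.27 (percentile 0.56), with Nop16 (-0.86), Wdr12 (-0.54), Polr1a (-0.46) and Ppan (-0.38) low. The remaining functional lists lay inside the middle 95% of random lists: interferon gamma response -0.15 (percentile 6.32; Socs1 -1.18, Irgm1 -0.74, Gbp5 -0.48), and proliferation -0.01 (percentile 71.8; Ccnb1 0.61, Mki67 -0.45, Cenpa -0.42, Mcm2 0.39). So did glycolysis at 0.08 (percentile 89.9; Pfkp 1.21, Slc2a3 0.89, Eno1 0.44, Pfkfb3 -0.43), sterol synthesis at 0.09 (percentile 94.8; Stard4 -0.65, Fdps -0.63, Dhcr7 0.23), the unfolded protein response at -0.14 (percentile 9.46; Herpud1 -0.36, Hspa5 -0.30, Pdia4 -0.26, Xbp1 -0.15) and mitochondrially encoded genes at -0.25 (percentile 4.14; mt-Nd2 -0.41, mt-Nd5 -0.38). The sterol and proliferation lists had a mean of the other sign from their median (-0.09 and 0.0068). Y-linked genes were measured in all 3 libraries, with a list median of -0.44 (percentile 4.04; Kdm5d -0.85, Uty -0.56, Ddx3y -0.32, Eif2s3y -0.03).

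The same equal weighing of clusters moved most other list medians towards 0. The interval over the members still excluded 0 for mature NK genes (0.48, 0.35 to 1.83), immature NK genes (-0.23, -0.52 to -0.07), immediate early genes (-0.23, -0.42 to -0.02), NF-kB targets (-0.32, -0.51 to -0.07), type I interferon (-0.40, -0.58 to -0.08) and heat shock genes (-0.40, -0.62 to -0.28). It held 0 for ILC1 genes (-0.18, -0.58 to 0.0074), cytokines (-0.0057, -0.55 to 0.30), activation markers (-0.10, -0.39 to 0.30) and TGF-beta response genes (-0.35, -1.07 to 0.23). It also held 0 for ribosome biogenesis (-0.14, -0.26 to 0.12), T cell markers (-0.42, -1.81 to 0.28) and myeloid markers (-0.11, -0.45 to 0.30). IL-2 and STAT5 targets (0.04, -0.09 to 0.31) and inhibitory receptors (0.25, -0.11 to 0.49) changed sign, with intervals that held 0. Proliferation genes changed sign and lay further from 0 (0.30, 0.05 to 0.42). Glycolysis genes (0.22, -0.03 to 0.48) and lung epithelial markers (0.87, -0.29 to 3.30) also moved away from 0, with intervals that held 0.

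**Figure D2:**
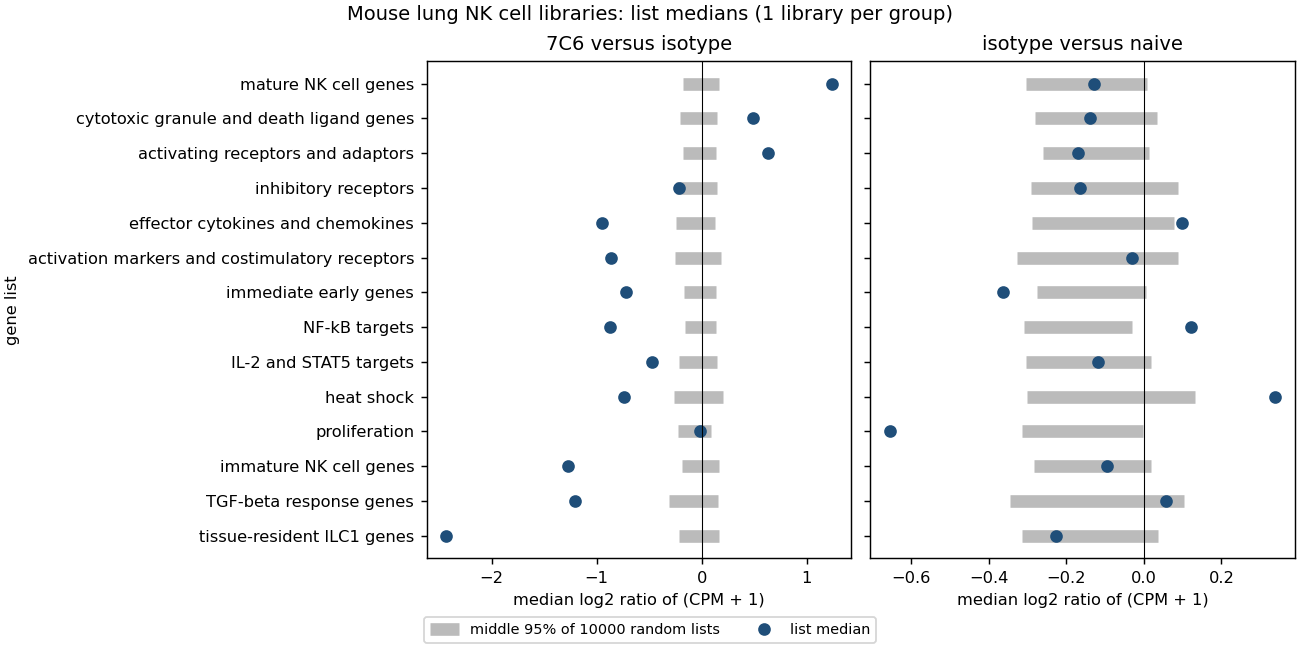
Median log2 ratio of (CPM + 1) of 14 gene lists in the mouse libraries, 7C6 over isotype on the left and isotype over naive on the right, on different horizontal scales; points are list medians and grey bars the middle 95% of 10000 random lists (1 library per group). The mature NK cell genes lie at 1.24 and the ILC1 genes at -2.43 on the left, against -0.13 and -0.23 on the right.

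The share of compared cells with a UMI was counted for some of these genes. Of the genes given, Prf1 and Ifng fall outside the naming rule and were added after the data were seen. After thinning, Gzmb was seen in 58.2% of 7C6 cells (56.5 to 59.9), 12.9% of isotype cells (11.6 to 14.4) and 10.6% of naive cells (9.44 to 11.8), and before thinning in 74.6%, 19.3% and 18.6%. Klrg1 was seen in 23.9% (22.5 to 25.4), 2.84% (2.21 to 3.60) and 3.44% (2.78 to 4.2), and before thinning in 42.0%, 6.03% and 7.85%. Perforin (Prf1) was seen in 13.1% (12 to 14.3), 3.35% (2.66 to 4.16) and 4.30% (3.56 to 5.14), and before thinning in 26.6%, 7.85% and 10.5%. The chemokine receptor Cxcr6 of resident cells was seen in 3.31% (2.73 to 3.99), 21.0% (19.4 to 22.7) and 26.7% (25 to 28.4), and before thinning in 6.04%, 35.4% and 41.9%. Ifng was seen in 18.3% (17 to 19.7), 17.9% (16.4 to 19.6) and 19.3% (17.8 to 20.8), and before thinning in 34.3%, 32.4% and 37.2%. As background, 203 B-, epithelial- and macrophage-like naive cells with a median of 4340 UMIs held Gzmb in 4.93%, Klrg1 in 0.985%, Prf1 in 1.97%, Cxcr6 in 12.3% and Ifng in 9.36% before thinning, against a median of 2626 UMIs in the compared naive cells. The unthinned Cxcr6 share of the 7C6 cells was below that background. Such cells numbered 9 in the 7C6 library and 5 in the isotype library, too few for a background share. Median depths of the compared cells were 2382 UMIs in the 7C6 library and 2384 in the isotype library.

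**Figure D3:**
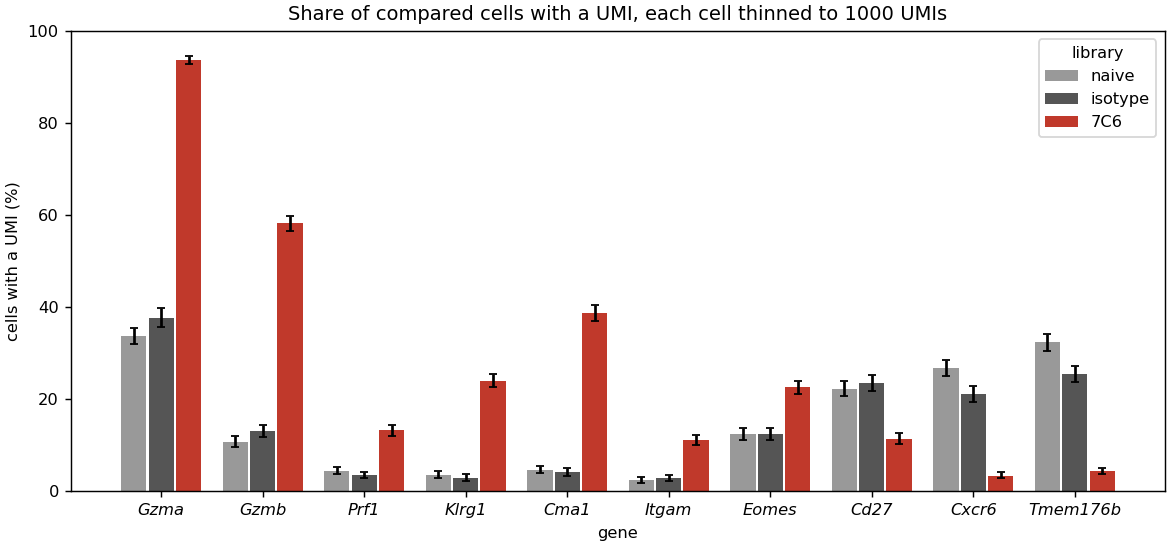
Share of compared mouse cells with at least 1 UMI of each of 10 genes, in percent, after thinning each cell to 1000 UMIs; bars are the naive, isotype and 7C6 libraries (1 per group) and error bars exact Clopper-Pearson intervals of counting error. Gzmb was seen in 58.2% of 7C6 cells against 12.9% of isotype cells, and Cxcr6 in 3.31% against 21.0%.

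The comparison of the isotype and naive libraries asked what the tumour cells together with the control antibody go with in lung NK cells. With 1 library per group, neither can be told apart from other differences between these libraries, such as handling. The maturation lists lay inside the range of random lists: mature NK genes at -0.13 (percentile 67.8; Prdm1 0.66, Klf2 -0.62), immature NK genes at -0.09 (percentile 74.7; Kit 0.97, Cxcr3 -0.48) and ILC1 genes at -0.23 (percentile 22.7; Ckb -0.57, Tmem176a -0.50, Tmem176b -0.47, Cxcr6 -0.39). Proliferation genes were lower in the isotype library (median -0.66, percentile 0; 21 of 23 lower), such as Cdc20 (-1.41), Ccnb1 (-1.37), Ccnb2 (-1.07) and Mcm2 (-0.87), and so were glycolysis genes (median -0.42, percentile 0.015), such as Slc16a3 (-0.95), Hk1 (-0.69) and Pfkp (-0.65). Heat shock genes were higher (median 0.34, percentile 99.9), with Hspa1b at 420 (404 to 436) and 124 (116 to 132) CPM, and cytokine genes lay slightly above the random range (median 0.10, percentile 98.3), with the chemokine Ccl4 at 1599 (1568 to 1630) and 803 (784 to 823) CPM. The median over all genes was -0.15, and -0.03 with TMM factors, so that ratios near -0.15 mark genes that moved with the rest. The ILC1-like cluster 2 and the NK-like cluster 1 together hold most of the compared cells of both libraries.

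Immediate early genes were lower in the isotype library (median -0.36, percentile 0.06), with Fosb (-1.29), Egr1 (-1.17) and Zfp36 (-1.03) low and Nr4a3 (1.12) high, and NF-kB targets were divided, with a median of 0.12 (percentile 99.98; Bcl2a1d 0.69, Bcl2a1b 0.55, Nfkbia -0.54, Rel 0.43) that was -0.00463 with a minimum of 1 CPM. Besides Hspa1b (1.75), the 10 largest ratios were Wdr89 (1.62), the chemokine receptor Cxcr4 (1.36), mt-Nd3 (1.34), Rps28 (1.13), Rps27rt (1.27) and 4 predicted genes, Gm9844 (1.38), Gm9843 (1.24), Gm10076 (1.14) and Gm8186 (1.13). Mitochondrially encoded genes had a median of 0.37 (percentile 99.8). Lists inside the random range were cytotoxic genes (-0.14, percentile 48.1; Stxbp2 -0.70, Lamp1 -0.59, Gzmb 0.54), activating receptors (-0.17, percentile 26.5; Ncr1 -0.49, Itgb2 -0.41), and inhibitory receptors (-0.16, percentile 30.1; Lair1 -0.47, Cd96 -0.42). So were activation markers (-0.03, percentile 87.8; Tnfrsf9 0.54, Cd69 -0.49), type I interferon (-0.24, percentile 13.5; Ifi27l2a -1.94, Ifit1 -1.10), interferon gamma response (-0.15, percentile 54.1; Gbp2 -0.78, Tap2 -0.56), and IL-2 and STAT5 targets (-0.12, percentile 68.7; Osm -1.02, Socs3 -0.56). The same held for ribosome biogenesis (-0.19, percentile 39.8; Pes1 -0.65, Bop1 -0.60), sterol synthesis (-0.21, percentile 26.5; Fdft1 -0.81, Mvd -0.76), the unfolded protein response (-0.33, percentile 5.75; Hspa5 -0.80, Ddit3 -0.49), TGF-beta response (0.06, percentile 95.7; Pmepa1 1.03, Rgs16 1.00) and Y-linked genes (0.19, percentile 95.4). The immature NK list had a mean of the other sign from its median (0.0074).

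Several of the smallest ratios of isotype to naive belong to marker genes of other cell types. S100a8 and S100a9, abundant in neutrophils, had 0 UMIs in the isotype library, which allows up to 0.559 CPM, and stood at 181 (172 to 190) and 117 CPM in the naive library, where 11 cells held 1404 of the 1454 S100a8 UMIs. The surfactant gene Sftpc stood at 0.454 (0.0937 to 1.33) and 164 (156 to 174) CPM, Scgb1a1 of airway cells at 0.909 and 97.1 CPM, and Lyz2 of myeloid cells at 3.18 and 62.9 CPM. Il1b (-5.47), Cxcl2 (-2.02), Cd74 (-1.49), Fosb and Arg1 (-1.19) complete the 10 smallest. The list medians were -5.45 for neutrophil markers and -4.61 for lung epithelial markers with genes at 0 UMIs set to 3 UMIs, and -5.99 and -4.88 with the pseudocount alone (percentile 0 for both). They were -0.64 for T cell markers (percentile 0.02; Cd3e -0.77, Cd3d -0.67) and -0.25 for macrophage, monocyte and dendritic cell markers (percentile 16.3; H2-Aa -2.95, H2-Ab1 -1.63). Between 7C6 and isotype, T cell markers had a median of -1.27 (percentile 0.02; Cd3e -1.96, Cd3g -1.57), myeloid markers -0.75 (percentile 0.01; Plac8 -1.90, Ccr2 -0.77), reversed to 0.018 over all cells, and epithelial markers 0.25 (percentile 95; Scgb1a1 3.43). S100a8, S100a9 and Retnlg had 0 UMIs in both of those libraries, so that no ratio can be given, and G0s2 stood at 23.7 and 5.15 CPM. No B cell or melanoma marker reached 10 CPM in the compared cells. Lists with 1 or 2 measured genes have no median: Pecam1 of endothelium (24.7, 39.1 and 37.0 CPM in the 7C6, isotype and naive libraries), Gsn of fibroblasts (3.03, 12.7 and 20.01), and Hbb-bs and Hba-a1 of red cells (14.7 and 12.4 CPM in the naive library).

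Cells in clusters named for other lineages were most frequent in the naive library, although the sort excluded CD3e- and TCRb-positive cells. The T-like names rest on transcripts such as Cd3d, Cd3e and Cd3g among the top genes, and whether these cells are T cells was not tested. T-like cells made up 2.29% of the cells kept in the 7C6 library (95% interval 1.82 to 2.85), 9.45% (8.37 to 10.6) in the isotype library and 24.4% (23.1 to 25.8) in the naive library. Epithelial-like cells made up 0.147% (0.0478 to 0.343), 0.187% (0.0607 to 0.435) and 1.63% (1.25 to 2.08). Macrophage-like cells numbered 4, 0 and 98, and B-like cells 0, 0 and 43. All these cells were set aside from the comparisons.

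The comparison of the 7C6 and naive libraries shares the 7C6 library with the comparison against isotype, so their values are not independent. Mature NK genes had a median of 1.61 (percentile 100; 14 of 15 higher), with Klrg1 at 323 (311 to 335) and 38.8 (34.6 to 43.3) CPM, and ILC1 genes had -2.81 (percentile 0; 13 of 13 lower). Immature NK genes stood at -1.29 (percentile 0) and TGF-beta response genes at -1.08 (percentile 0). Cytotoxic genes stood at 0.19 (percentile 99.9) and activating receptors at 0.44 (percentile 100), while inhibitory receptors stood at -0.42 (percentile 0.26) and at 0.65 over members with at least 50 CPM. Stimulation lists were low: cytokines -1.07 (percentile 0), activation markers -0.92 (percentile 0), and immediate early genes -1.05 (percentile 0; 21 of 21 lower). So were NF-kB targets -0.75 (percentile 0), IL-2 and STAT5 targets -0.70 (percentile 0), type I interferon -0.52 (percentile 0.15), interferon gamma response -0.31 (percentile 1.82) and heat shock -0.55 (percentile 0.04). Proliferation was at -0.56 (percentile 0.02; 23 of 23 lower) and ribosome biogenesis at -0.45 (percentile 0.03). Glycolysis (-0.26, percentile 10.5), sterol synthesis (-0.47, percentile 3.89), the unfolded protein response (-0.36, percentile 2.90), mitochondrially encoded genes (0.02, percentile 77.3) and Y-linked genes (-0.25, percentile 31.0) lay inside the random range. Markers of T cells (-1.76, percentile 0.01), myeloid cells (-1.0, percentile 0), neutrophils (-5.58 with genes at 0 UMIs set to 3 UMIs) and lung epithelium (-3.02, percentile 0) were low. The median over all genes was -0.17, and 0.05 with TMM factors. Clusters 0 and 2 hold most of the compared 7C6 and naive cells, respectively.

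The last comparison asked whether the genes called in human NK cells were displaced in the mouse libraries. Of the 316 human genes that rose, 192 had a mouse gene of the same symbol at 10 CPM or more, and these were lower in the 7C6 library than in the isotype library, with a median log2 ratio of -0.20 (interval -0.33 to -0.13, percentile 0; 64 higher and 128 lower). The median was -0.46 over genes with a bulk fold of at least 1.5 and -0.10 with TMM factors. Cd83 and Il2ra lie far below these medians: CD83 and IL2RA rose in culture, and their mouse counterparts stood at log2 ratios of -2.83 and -2.28. All these mouse ratios pool cells of different clusters, and the risen genes were not weighed at equal cluster shares. With such weighing, the list of activation markers, which holds Cd83 and Il2ra, went from -0.86 to -0.10 (interval over members -0.39 to 0.30). IFNG also rose in culture, while Ifng stood at -0.05, as did the median over all genes. Of the 284 human genes that fell, 57 were measured, with a median of -0.16 (percentile 9.07; 20 higher and 37 lower), or -0.07 with TMM factors. Over fallen genes with a bulk fold of at least 1.5, 27 were measured, with a median of -0.34 (percentile 0.695; 7 higher and 20 lower). Species, antibody form, time of exposure and setting differ between the experiments, and the difference between them was not tested.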

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

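The corrections for GC content and length, the library quality weights, the limit on UMIs per cell and the set-aside of cluster 1 were chosen after the data were seen. Against 600 bulk genes past the threshold (316 rose, 284 fell), DESeq2 gave 1027 (527 and 500), the stricter low-count filter 186 falls, an adjusted p under 0.01 178 (116 and 62), a fold of at least 1.5 391 (175 rises), limma with the GC and length correction 1428 (916 and 512), and library quality weights 3302 (1683 and 1619). Leaving out each library gave 116 to 1994 genes, 78 to 965 rises and 38 to 1029 falls. No gene list passed with an estimated correlation (0 lists). The stricter thresholds pass fewer genes by construction; for the other changes the cause was not tested. Of the comparisons of named bulk genes with an alternative, 765 kept their direction and side of the threshold, 90 dropped below it and 4 newly passed it. In the other 7 the sign turned, for genes that never passed: KLRK1 lay between -0.41 and 0.26, CD79A between -0.27 and 0.067 and CD79B between -0.17 and 0.032 with a library left out. The type I interferon list, which passed in no directional test, turned direction in 3 fits (adjusted p = 0.97 with the replicate block, 0.78 to 0.98 over left-out libraries). In the directional rotation test fry, activating receptors (adjusted p = 0.020) and NKG2D ligands (0.012) newly passed. The mixed test of fry, which asks for no direction, passed every list (type I interferon 0.00028) but T cell (0.21) and myeloid markers (0.27).

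With the replicate number as a block, 155 genes passed (102 rose and 53 fell), 17 of the 58 named genes past the threshold no longer passed, the cytotoxic list did not pass (adjusted p = 0.054), and 165 genes fell in the fit with the GC and length correction. No pairing by number was seen: the deviations of isotype and 7C6 libraries of the same number correlated at 0.0018, -0.34 and -0.17, and samples did not correlate best with their own number. So few libraries cannot exclude a pairing, and the labels do not say whether the numbers mark shared cultures.

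For the mouse list medians, 304 of the planned values for 7C6 versus isotype, 297 for isotype versus naive and 291 for 7C6 versus naive stayed near the reported value. For 7C6 versus isotype the others were type I interferon 0.090 (at least 50 CPM; direction turned), macrophage markers 0.018 (all cells; direction turned), ribosome biogenesis -0.36 (totals without ribosomal and mitochondrial genes), sterol synthesis 0.21 (TMM) and ILC1 genes -2.74 (cluster 1 also set aside). For isotype versus naive, all cells together gave cytotoxic genes 0.027, activating receptors 0.049, inhibitory receptors -0.011, T cell markers -1.52 and epithelial markers -7.23. TMM gave activating receptors -0.041, inhibitory receptors -0.035 and the unfolded protein response -0.20. A minimum of 1 CPM gave NF-kB targets -0.00463 (direction turned), and a pseudocount of 0.1 CPM neutrophil markers -9.29 and epithelial markers -6.95. For 7C6 versus naive, a minimum of 50 CPM gave inhibitory receptors 0.65 (direction turned) and type I interferon -0.30. TMM gave type I interferon -0.30, interferon gamma response -0.085, proliferation -0.34, ribosome biogenesis -0.24, the unfolded protein response -0.14 and Y-linked genes -0.038. All cells gave interferon gamma response -0.19, proliferation -0.32, the unfolded protein response -0.22 and T cell markers -3.37. ILC1 genes stood at -2.97 (thinned), -2.98 (mean over cells) and -3.10 (cluster 1 also set aside), proliferation at -0.75 and Y-linked genes at -0.37 with cluster 1 also set aside, and Y-linked genes at -0.036 when thinned. Pseudocounts of 0.1 and 5 CPM gave neutrophil markers -9.29 and epithelial markers -2.02. The human genes that rose stood at -0.46 (bulk fold of at least 1.5) and -0.10 (TMM) in the mouse libraries. TMM shifts all genes alike, and a smaller pseudocount widens ratios against 0 by construction; otherwise the cause was not tested. Of the planned comparisons of single mouse genes with an alternative, 318 stayed near the reported value and 82 moved; of those added later, 59 stayed and 21 moved. Most moves came with all cells (18), a pseudocount of 5 CPM (18) and cluster 1 also set aside (17).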

Other observations

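A small cluster among the compared mouse cells, cluster 7, was named NK-like because no other class was found and 14 NK markers reached 50 CPM in it, with 1 of them among its top 25 genes. It has Ccl4, Nfkbid, Gadd45b, Ccl3, Xcl1, Icam1 and Nr4a3 at the top of its genes, which are chemokines and genes of recent stimulation. It held 0.604% of the compared 7C6 cells (20 cells), 1.82% of the isotype cells (44 cells) and 0.0748% of the naive cells, and a cluster drawn mostly from 1 library may be a property of that library. Some maturation genes, chosen after their values were seen, were also counted cell by cell. After thinning, the transcription factor Eomes was seen in 22.5% of 7C6 cells (21.1 to 24.0), 12.3% of isotype cells (11 to 13.7) and 12.3% of naive cells (11.1 to 13.6), and before thinning in 42.0%, 24.5% and 27.2%, against a background of 2.46% in 203 naive cells of other lineages with a median of 4340 UMIs. Cd27, like Eomes a member of the immature NK cell list, was seen in 11.3% (10.3 to 12.5), 23.5% (21.8 to 25.2) and 22.2% (20.6 to 23.8), and before thinning in 24.3%, 47.4% and 47.2%, against a background of 12.8%. The NK receptor gene Ncr1 was seen in 68.9% (67.3 to 70.5), 49.6% (47.6 to 51.7) and 61.9% (60.0 to 63.7) after thinning, and before it in 91.3%, 75.6% and 87.5%, against a background of 22.7%.

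Some human genes of interest lie outside the naming rule and were chosen after their values were seen. MICA, a target of the antibody, stood at 16.7 ± 0.835 and 17.5 ± 2.57 CPM (adjusted p = 0.75), and MICB at 44.4 ± 1.88 and 44.7 ± 0.544 CPM (adjusted p = 0.95), in the isotype and 7C6 groups. PRF1 (perforin) stood at 1887 ± 54.9 and 1965 ± 112 CPM (adjusted p = 0.60), and GZMB (granzyme B) at 962 ± 44.4 and 1012 ± 152 CPM (adjusted p = 0.69). Over all mouse cells kept, other lineages included, the melanocyte genes Pmel and Dct had 1, 0 and 2 and 0, 3 and 0 UMIs in the 7C6, isotype and naive libraries.

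All tests below were chosen after the results were seen. Only 10 splits of the 6 bulk libraries exist, too few for a share under 0.05; the real split gave 600 genes and was the 1 with any, and the highest other gave 0.

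The genes that fell in the bulk data may come from A375 RNA in the sorted cells. The mean log2 change of the melanoma markers was -1.35 (SD 0.42 over the markers), and fewer surviving A375 cells and a cleaner sort predict the same fall and cannot be told apart. Fallen genes outside the melanoma list had a median within-group slope on these markers of 0.43 after the GC and length correction, above the upper quartile of genes not past the threshold (0.23), but 0.18 before it, below that quartile (0.32), so the slopes leave the question open. GC content and length could not account for all falls, since 79.0% of them stayed past the threshold after the correction. Of the 284 fallen genes, 24 fell further than the marker mean by over 2 SE, and loss of expression in NK cells themselves was not separated from these.

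7C6 replicate 2 stands apart from its group, at 39.5 on the first principal component (55.0% of variance) against 12.5 and 6.39 for the other 7C6 libraries, and with a quality weight of 0.141. GC content and transcript length may be part of this. They account for 40.4% of the variance of its deviation from the mean of all other libraries, against at most 26.0% for any other library. The group difference is inside this deviation, since that mean includes the isotype libraries. A mislabelled isotype library is argued against, since 80.5% of 1965 genes called without it lie on the 7C6 side in it. The labels give no biological difference for this library, and no biological explanation was tested.

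The mouse lists that separate the 7C6 and isotype libraries could reflect a changed mix of cells, a changed state of each cell, or the libraries themselves. Depth is argued against, as the ratio of median UMIs per compared cell was 0.999. At equal shares of clusters found without the listed genes, the mature NK median went from 1.24 to 0.48 (interval over members 0.35 to 1.83). The shares of these clusters could thus be part of the difference, while some of it remained at equal shares. This interval is over list members and covers neither cells nor libraries. Within single clusters the mature NK interval excluded 0, except in that with 1496 7C6 and 53 isotype cells (0.39, -0.07 to 0.65). Finer states inside the clusters were not weighed, so a changed mix of cells is not excluded as the whole cause. The ILC1 median at equal shares was -0.18 (-0.58 to 0.0074), an interval that held 0. The ILC1 genes stood highest in the cluster with 252 7C6 and 1256 isotype cells, where their median was -0.09 (-0.53 to 0.06). The equal-share value may mostly reflect that cluster, so it does not settle whether cluster shares account for the ILC1 difference. Within the cluster most filled by both libraries (1519 and 1078 cells), however, the ILC1 median was -1.53 (-2.03 to -1.01), and finer states inside that cluster could remain. The other clusters held few cells of at least 1 library. Their ILC1 medians were -0.71 (-2.37 to 1.70, 1496 7C6 and 53 isotype cells) and -2.54 (-3.48 to -1.30, 47 and 33 cells). With 1 library per group, the antibody and any other difference between the 2 libraries, such as handling, cannot be told apart.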
